A study of Arabidopsis thaliana with 6 samples.

How the data were processed

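Total RNA of 14-day-old Arabidopsis thaliana seedlings was hybridised to 6 one-colour Agilent arrays, 3 from plants that overexpress sORF2146 and 3 from plants that carry the empty vector. Per the labels' protocols, plants grew under 14 hours of light and 10 hours of darkness, and Cy3-labelled cRNA was made from 200 ng of RNA. Each replicate is a separate biological replicate by the series' own description.

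The scanner files hold spot intensity made with Agilent Feature Extraction 11.5.1.1, per the file headers. The processed signal is the intensity after the software subtracted background and removed spatial trends within each array, per the file headers, and it is not normalized between arrays. The raw median intensity of a spot and of its local background, and the software's flags, which are other values of 0 or 1 per the file headers, were also used. A deposited table of the whole series holds linear intensity with no method stated in the sources used here. Its sorted values were equal in all 6 columns for 96.3% of ranks within a relative tolerance of 1e-06, so it was treated as quantile normalized, and the median of every column was 120.9.

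The log2 processed signal of each array was reduced by that array's 75th percentile over the 35635 probes that are not controls. Spots flagged as outliers were set to missing. A probe entered the test if it was well above background on all 3 arrays of at least 1 group, which 23523 probes were. A gene was represented by its probe with the highest mean, and probes whose name joins a clone and 1 locus were assigned to that locus. Of 35475 gene identifiers, 26415 matched a row of the RefSeq gene table for TAIR10.1, as did 89.6% of the 23394 genes tested. Symbols come from that table or from lists fixed in advance, and a gene is named by its locus identifier otherwise.

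Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values below come from this test. Changes are log2 differences, overexpressor minus vector control. A gene not well above background on any array of a group has only a bound, given as at least N-fold. The bound sets the brighter group's mean against a raised mean of the dimmer group. Per array, that mean took the higher of the lowest signal well above background and the probe's own signal. A bound holds for the main processing only and carries no error. Values under alternatives are fitted log2 differences and can lie below it. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 23 lists with enough measured members. Of 598 list members, 7 were dropped because their symbol did not match their locus in the gene table. Figures were drawn with matplotlib 3.10.9.

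The lists, the tests of the report and the rule for the genes named were chosen before the data were examined, and the closing section says which of its tests were not. The rule took the 12 named genes with the largest rise and the 12 with the largest fall among genes that passed the test with groups that did not overlap and with the brighter group well above background, up to 4 members of each list with the smallest adjusted p, and FT, SOC1, FLC, SVP, CO, LFY, AP1 and AOX1A. Other features are named as chosen after their values were seen.

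Between 65.3% and 68.8% of probes were well above background on an array, no spot was saturated, and the 75th percentile of the signal lay between 817 and 1170. The number of arrays limits the precision. On simulated data with the spread of these arrays, this comparison recovered 20.9% of genes changed by 0.5 on the log2 scale, 53.7% of those changed by 1 and 74.2% of those changed by 2, with 6 false calls among 23388 genes. The simulated noise was independent between genes and had the same SD in both groups, and few genes were changed. These rates may differ for real arrays, where genes vary together.

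Each group lay on a slide of its own, so slide and group cannot be told apart, and a fit with slide as a block was not possible. Alternatives covered the background correction, the normalization, the filter on dim probes, the summary of probes, the variance model, array weights, a replicate block and leaving out each array. The planned normexp correction was to use mean signals. The files used here hold median signals, which took their place. Background subtraction with an offset of 50 and gene-by-gene array weights were added after the data were seen, because the normexp fits differed between arrays and the default array weights did not converge.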

Results

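Gene expression was measured in 14-day-old Arabidopsis seedlings that overexpress sORF2146, a short open reading frame, and in seedlings transformed with the vector alone. The series asks what physiological role sORF2146 has, and its title concerns flowering. There were 3 arrays per group. Between 23270 and 24510 probes were well above background on each array.

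None of the probes carries the name sORF2146, so its level is not reported by name and the labels could not be checked against it. The list of short open reading frames fixed in advance had no measured member for the same reason.

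Pairwise correlations across genes ranged from 0.988 to 0.994 among the overexpressor arrays, from 0.969 to 0.989 among the control arrays, and from 0.945 to 0.984 between groups. The first principal component held 61.7% of the variance, and vector control replicate 1 lay farthest from the other arrays on it. The median SD of a gene was 0.12 in the overexpressor and 0.17 in the control on the log2 scale, and the control SD was the larger for 65.3% of genes.

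MAF4 and MAF5, floral repressors of the MADS-box family, were higher in the overexpressor. MAF4 rose by 2.17 on the log2 scale (SE 0.10, n = 3 per group, limma adjusted p = 0.0018). MAF5 rose by at least 1.59-fold (limma adjusted p = 0.030), as it was not well above background on any control array. Under the alternatives run, MAF4 passed in 17 of 18 with a lowest value of 1.35. MAF5 passed in 10 of 17 with a lowest value of 0.46 on the log2 scale, which is below its bound. FLC, the central repressor of the vernalization pathway, differed by 4.78 (SE 1.23) and did not pass the test (limma adjusted p = 0.074). It passed in 4 of the 17 alternatives that tested it, with values between 2.65 and 7.06. Its 3 overexpressor values lay between -0.33 and 0.11, while the control values were -2.57, -7.65 and -4.63, the second of these not well above background. Of 23 measured floral repressors, 2 rose and 0 fell, both over all genes and adjusted over the list alone, and the list median was 0.09 (camera adjusted p = 0.41).

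Among 15 measured floral activators and integrators, 0 rose and 1 fell over all genes, while 1 rose and 1 fell adjusted over the list alone, and the list median was 0.12 (camera adjusted p = 0.90). The one that fell was FUL, a MADS-box gene of floral commitment, at -0.97 (SE 0.11, limma adjusted p = 0.025). Its signal was dim, and its difference was 0.03 with background subtraction and 0.07 with normexp, both with an offset of 50 that draws dim values together. FT, which encodes the mobile floral signal, differed by -2.21 (SE 0.69, limma adjusted p = 0.10), and its other probe gave -2.27. CO, an activator of FT, differed by -1.38 (limma adjusted p = 0.14). FT and CO each passed in 3 of 18 alternatives, with values from -2.93 to -1.05 and from -2.05 to -0.27. SOC1 differed by 0.12 and SVP by 0.10, and neither passed. LFY and AP1 were not well above background on any array and were not tested. Of 6 measured floral organ identity genes, SEP1 fell by at least 1.11-fold (limma adjusted p = 0.028), and adjusted over the list alone 1 rose and 3 fell. SEP1 was also dim, with a difference of 0.13 with that subtraction and 0.15 with normexp.

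**Figure D1:**
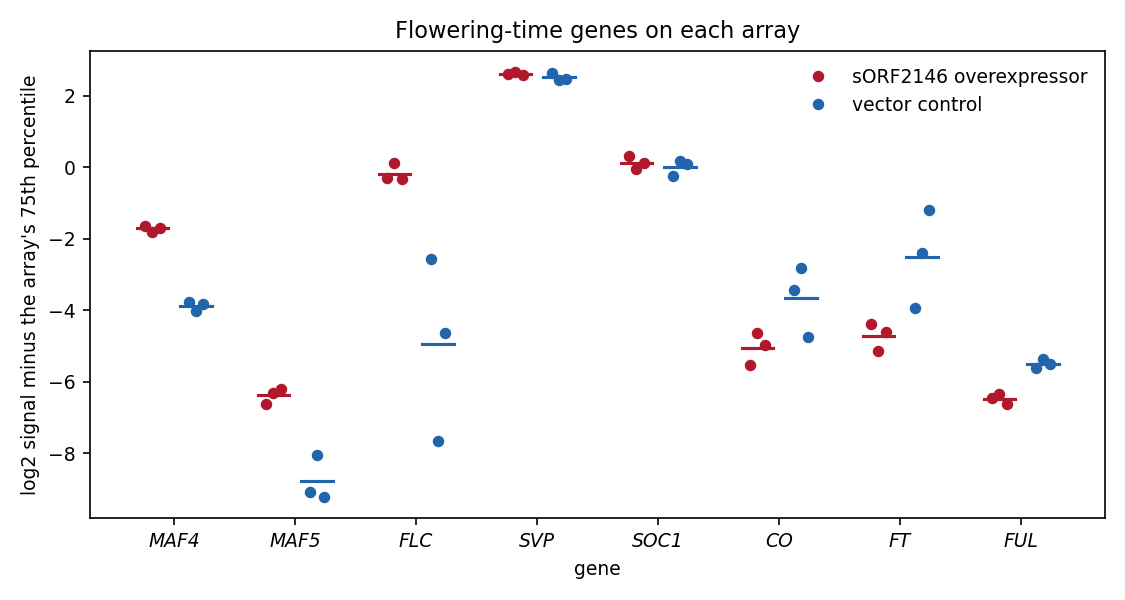
Signal of 8 flowering-time genes (log2, relative to the 75th percentile of each array) on each of the 3 overexpressor arrays (red) and 3 vector control arrays (blue), with lines at the group means. The groups of MAF4 lie apart with little spread, while the control values of FLC run from -7.65 to -2.57.

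Over all 23394 genes tested, 588 rose and 621 fell, 1209 in total. By fitted value 92 rose and 315 fell by 2-fold or more, and 15 rose and 109 fell by 4-fold or more. With genes that have only a bound counted at that bound, these were 87 and 283 by 2-fold and 13 and 78 by 4-fold. At an unadjusted p under 0.05 there were 7207 genes. The groups did not overlap for 40.6% of genes, where chance gives 10% for a single gene. Genes vary together and each group lay on its own slide, so the share could lie far from 10% by chance or by slide. Quantile normalization gave 779 genes that rose and 488 that fell, and the 75th percentile over detected probes gave 403 and 620. The count depended on single arrays: it was 46, 49 and 51 without overexpressor replicate 1, 2 and 3, and 35 without vector control replicate 2, but 1190 and 1191 without vector control replicate 1 and 3. It was 4 with normexp, whose fitted background differed widely between arrays, and 188 with no filter on dim probes.

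The largest rises among named genes included PAP25 and PAP24, purple acid phosphatases. PAP25 rose by at least 16.6-fold (limma adjusted p = 0.028), and PAP24 rose by 3.72 (SE 0.58, limma adjusted p = 0.036). MRD1 rose by 3.90 (SE 0.11, limma adjusted p = 0.00037). Its neighbour HEI10 rose by 3.05 (SE 0.18) at the probe used, but the other HEI10 probe differed by -0.01, so the gene's change is uncertain. AGL44, a root MADS-box gene of the nitrate response, rose by 1.95, SRO4 by 1.87, GPAT7 by 1.40, AGP17 by 1.34 and WRKY43 by 1.27. FTSH6 rose by at least 1.84-fold. AGL44, SRO4, GPAT7, AGP17 and WRKY43 passed in 12, 10, 13, 11 and 11 of the 18 alternatives run, and the lowest values of AGL44, SRO4, GPAT7 and WRKY43 were 0.88, 1.14, 0.60 and 0.63. MRD1 passed in all 18, but PAP25 passed in 10 of 17, PAP24 in 9 of 17 and FTSH6 in 9 of 17, with lowest values of 1.36, 1.31 and 0.39. On the log2 scale, those of PAP25 and FTSH6 lie below their bounds. The bound of PAP25 was 10.6-fold without overexpressor replicate 2.

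Among the largest falls of named genes, LTP4, a lipid transfer protein, stood first at -5.68 (SE 0.35, limma adjusted p = 0.0051). NDB4 and NDB3, alternative NAD(P)H dehydrogenases of mitochondria, fell, with differences of -4.52 and -4.11. WRKY46, a defence transcription factor, fell, at -4.26 (SE 0.58, limma adjusted p = 0.030). PUB54 at -4.57, NAC090 at -4.24, TIM17-1, a subunit of the mitochondrial import machinery, at -4.05 and NAC044 at -3.36 also fell. NAC085 fell by at least 9.39-fold, NOGC1 by at least 9.17-fold, MRN1 by at least 4.5-fold and NUC-L2 by at least 2.87-fold. These 4 passed in 5, 8, 7 and 9 of the 17 alternatives that tested them, with values closest to 0 of -0.80, -0.67, -0.41 and -0.28. These are log2 differences, and each is a smaller change than the gene's bound. LTP4 passed in 16 of 18 and came as close to 0 as -3.62. Without vector control replicate 1 the bounds of NAC085 and NUC-L2 were 6.18-fold and 1.81-fold, and that of NAC085 was 15.4-fold without vector control replicate 3. NDB3, well above background on 2 of 3 overexpressor arrays, passed in 9 of 17 and came as close to 0 as -1.32, and NDB4 passed in 11 of 18 and came to -2.43. WRKY46 and NAC044 each passed in 11 of 18, with values closest to 0 of -3.47 and -2.32. PUB54 and NAC090 were well above background on 1 of 3 overexpressor arrays, passed in 7 and 9 of 17 and came as close to 0 as -1.15 and -1.19, and TIM17-1 passed in 10 of 18 with a value as close to 0 as -1.85.

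**Figure D2:**
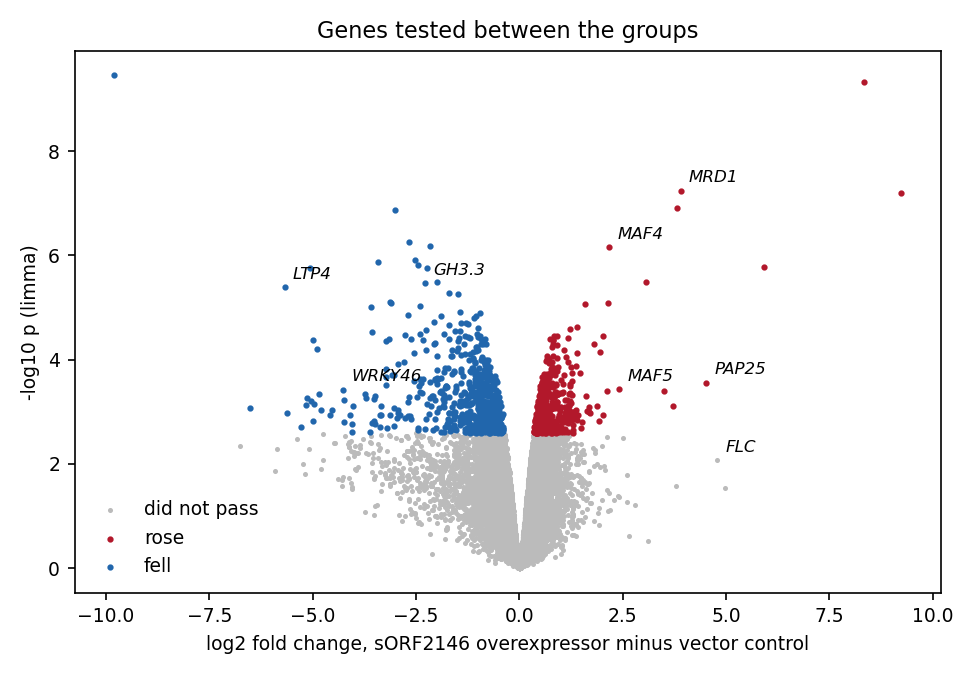
Difference between the groups (x axis, log2, overexpressor minus vector control) against -log10 of the limma p-value (y axis) for each gene tested, with the 588 that rose in red, the 621 that fell in blue and the rest in grey. Fitted falls of 4-fold or more outnumbered such rises by 109 to 15, and by 78 to 13 with genes that have only a bound counted at it.

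Genes of the mitochondrial dysfunction response were lower in the overexpressor, with a list median of -1.93. Of 18 measured members 2 fell and 0 rose, and 11 fell adjusted over the list alone (camera adjusted p = 1.3e-05, adjusted p = 0.70 with an estimated correlation). The members that fell were TIM17-1 and AT5G51440, a small heat shock protein gene, at -2.37 (SE 0.33), which passed in 11 of 18 alternatives. AOX1A, the alternative oxidase that marks this response, differed by -1.78 (SE 0.49, limma adjusted p = 0.083). The control arrays differed among themselves in this list, with median deviations of 2.00, 0.97 and -0.16 from the mean of the 6 arrays.

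Salicylic acid and pathogen defence genes had a median of -1.74. All 19 measured members were lower, 0 passed over all genes and 12 fell adjusted over the list alone (camera adjusted p = 7.4e-06, adjusted p = 0.70 with an estimated correlation). GRX480 differed by -3.65 and SARD1 by -3.26, and neither passed. The rapid touch and wound response had a median of -0.84, with 1 of 16 members, WRKY46, that fell and 2 that fell adjusted over the list alone (camera adjusted p = 0.00014, adjusted p = 0.70 with an estimated correlation). In both lists vector control replicate 1 lay highest of the arrays, and without it the medians were -0.94 and -0.49. The same array lay lowest in the root markers, at -0.86 from the mean of the 6 arrays. In the touch and wound list vector control replicate 3, at -0.31, lay among the overexpressor arrays, at -0.72, -0.27 and -0.30.

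Among 24 measured abscisic acid, drought and cold genes, HAI1 (-1.81) and RD20 (-1.996) fell, and the same 2 members passed adjusted over the list alone. Each passed in 12 of 18 alternatives, and HAI1 came as close to 0 as -0.998. The list median was -0.44 (camera adjusted p = 0.00094, adjusted p = 0.61 with an estimated correlation). In flavonoid and anthocyanin biosynthesis 4 of 16 members fell and 1 rose, and 6 fell and 1 rose adjusted over the list alone. LDOX (-0.91), DFR (-0.90) and TT19 (-0.97) fell, and MYBL2, a repressor of the pathway, rose by 0.76. LDOX, TT19 and MYBL2 each passed in 11 of 18 alternatives, and LDOX and TT19 came no closer to 0 than -0.78 and -0.82, while DFR passed in 7 of 18 and came to -0.38. The list median was -0.32 (camera adjusted p = 0.0034, adjusted p = 0.54 with an estimated correlation), and this was the one list called by the directional test of fry (adjusted p = 0.014). The mixed test of fry, which ignores direction, called 17 lists. The abscisic acid median was -0.33 without vector control replicate 1, its highest array, and -0.67 without vector control replicate 2. The flavonoid median was -0.51 without vector control replicate 1.

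Senescence genes had a median of -0.47 with 0 of 13 members past the test under either adjustment (camera adjusted p = 0.011, adjusted p = 0.62 with an estimated correlation). Aliphatic glucosinolate genes had a median of -0.24 with 0 of 16 past the test and 1 that fell adjusted over the list alone (camera adjusted p = 0.031, adjusted p = 0.80 with an estimated correlation). In the gibberellin list, median -0.24, GA20OX3, a biosynthetic oxidase, fell by at least 2.26-fold, though it passed in 9 of 17 alternatives and came to -0.0547 in 1 of them, and 2 of 19 fell adjusted over the list alone (camera adjusted p = 0.045, adjusted p = 0.61 with an estimated correlation). Plastid-encoded genes were slightly higher after scaling, with a median of 0.13. Of 85 members 5 rose and 0 fell, and 8 rose adjusted over the list alone (camera adjusted p = 0.00074, adjusted p = 0.80 with an estimated correlation), and the median was 0.0785 without vector control replicate 1. The spike-in RNA, compared below, was 0.27 higher at its median after the same scaling, so no plastid rise relative to it is shown. The glucosinolate call was lost without overexpressor replicate 1 or 2 or vector control replicate 3 (medians -0.16, -0.18 and -0.0203), and the gibberellin call without overexpressor replicate 1 or 3 or vector control replicate 2 or 3 (medians -0.23, -0.20, -0.20 and -0.19).

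**Figure D3:**
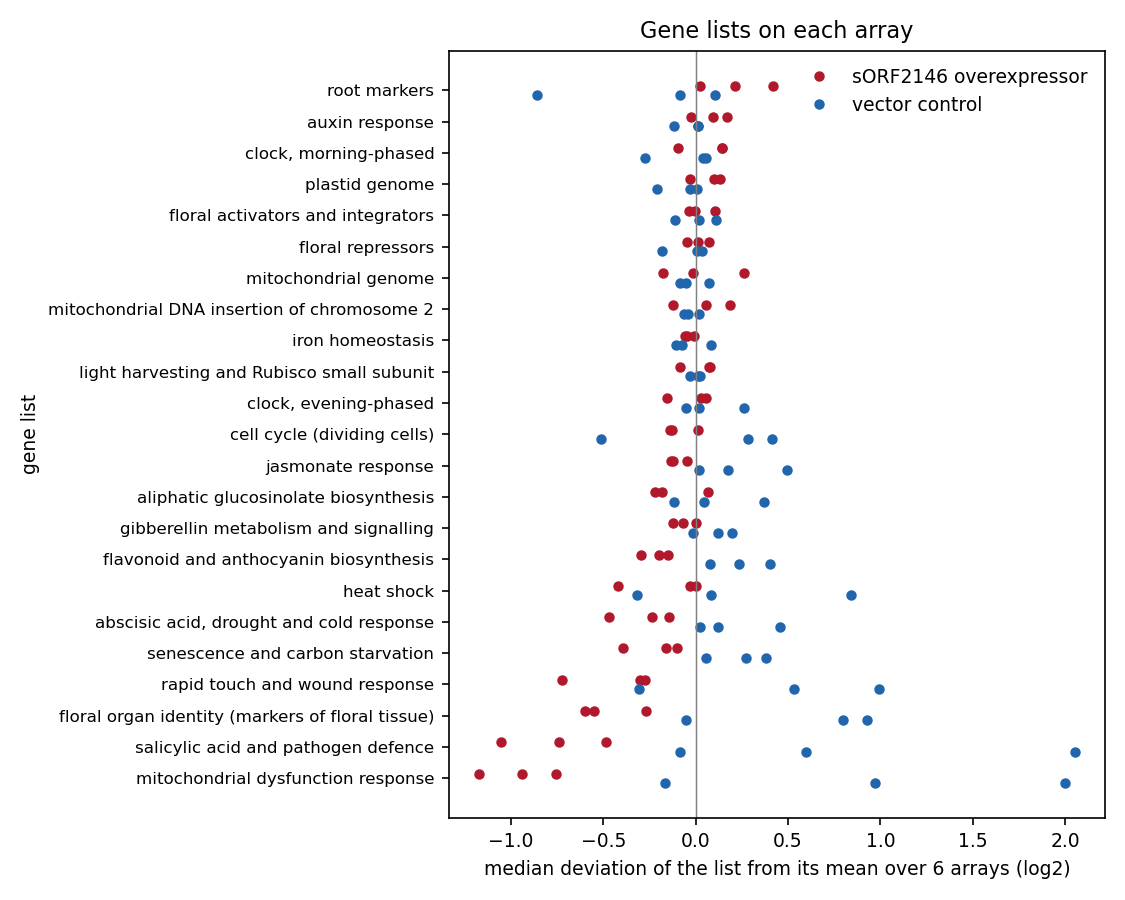
Median deviation of each gene list from its mean over the 6 arrays (x axis, log2) on the 3 overexpressor arrays (red) and the 3 vector control arrays (blue), with lists on the y axis ordered by their median difference. The control arrays spread from -0.16 to 2.00 in the mitochondrial dysfunction response.

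The other lists were not called by camera. Mitochondrially encoded genes had a median of 0.03 with 0 of 97 past the test, and the genes of the mitochondrial DNA insertion on chromosome 2 a median of 0.00 with 2 that rose and 1 that fell of 29. Morning-phased clock genes had a median of 0.21, where LNK2 rose by 0.75, passing in 8 of 18 alternatives, and the other 10 did not pass, and evening-phased clock genes a median of -0.07 with 0 of 9 past the test. In the auxin list GH3.3, an auxin-conjugating enzyme, fell by 2.29 (SE 0.13), and LBD29 rose by at least 1.83-fold, though it passed in 7 of 17 alternatives and its value of 1.14 came to 0.37. GH3.3 passed in 16 of 18. The jasmonate list had a median of -0.20 with CYP94B3 the one that fell, heat shock genes a median of -0.36 with DREB2A at -1.08 the one that fell, and the cell cycle list a median of -0.10 with CYCB1;1 at -0.80 the one that fell. Light harvesting genes had a median of -0.04, where LHCA2 rose by 0.62. CYP94B3, DREB2A, CYCB1;1 and LHCA2 passed in 10, 11, 12 and 11 of 18 alternatives, with values closest to 0 of -0.48, -0.70, -0.42 and 0.57. Of 17 root markers 16 were higher in the overexpressor, with a median of 0.41 and 0 past the test (camera adjusted p = 0.10). That median was 0.0803 without vector control replicate 1 and 0.69 without vector control replicate 3, where the list was called (camera adjusted p = 0.026). Iron genes had a median of -0.01, and 0 members passed. Of the seed markers 2 were measured, EM1, at least 24.6-fold apart with the control brighter (limma adjusted p = 0.059), and EM6 at -0.44, and neither passed. The EM1 bound was 8.85-fold without vector control replicate 1 and 77.7-fold without vector control replicate 3.

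Spike-in RNA, which is the same in every sample, was compared to look for a difference between the slides. The median of 8 spike-in probes was 0.27 higher in the overexpressor after scaling (exact two-sided permutation p = 0.4) and -0.05 different before it (exact two-sided permutation p = 0.8). The scaling moves every gene of an array alike. Small list medians and the counts of rises and falls therefore depend on this reference, as the plastid median does. Departures of the 8 probes from their median shift fell with brightness, from 0.14 for the dimmest to -0.23 for the brightest (Spearman rho -0.86 across probes, exact two-sided permutation p = 0.011). The 75th percentile used for scaling differed by -0.31 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). Negative control spots had a mean signal of 47.2 in the overexpressor and 48.3 in the control (exact two-sided permutation p = 0.4).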

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

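Background subtraction, gene-by-gene array weights and the bounds without single arrays were chosen after the data were seen. The 1209 calls were 4 with normexp (2 up and 2 down, all by 2-fold or more, and 4 shared with the 1209). Normexp put the mean background at -155 on overexpressor replicate 1 and at -158 on vector control replicate 2, against 14.7 to 18 on the other arrays. With background subtraction, which fits no such model, 1548 genes were called, 1014 up and 534 down (44 and 131 by 2-fold or more); 860 of the 1209 calls were shared and 59 changed sign. FUL, SEP1 and AT2G07750 turned to 0.0655, 0.15 and 0.14 with normexp and to 0.0296, 0.13 and 0.12 with subtraction. With no filter on dim probes 188 genes were called, 55 up and 133 down (31 and 108 by 2-fold or more), of 35475 tested. Trend and robust variance gave 1707 calls, 903 up and 804 down.

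Array weights gave 10001 calls, 5094 up and 4907 down (279 and 1055 by 2-fold or more), but their estimation stopped before converging. The gene-by-gene weights gave 5557 calls, 2877 up and 2680 down (196 and 800 by 2-fold or more). Weights are estimated from the same 6 arrays, and neither count is taken as a firmer result.

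The replicate block gave 14 calls, 6 up and 8 down, all by 2-fold or more. The labels do not say that the replicate numbers pair the samples, and each number was also the array's position on its slide. The deviations of same-numbered arrays correlated at -0.09, -0.0005 and -0.02, and not every array correlated best with its own number. These values showed no sign of pairing, but 3 arrays per group are too few to exclude it.

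Leaving out 1 array gave 35 to 1191 calls, 8 to 487 up and 27 to 826 down, and 8 to 92 up and 27 to 595 down by 2-fold or more. The lowest total came without vector control replicate 2, and the totals were 46, 49 and 51 without overexpressor replicates 1, 2 and 3. Without vector control replicate 1 or 3 the totals were 1190 and 1191, with 729 and 628 shared calls. A fit to fewer arrays has less power. These fits had equally many arrays, but power also depends on the spread among the arrays that are left. The 2 control arrays left without vector control replicate 2 correlated at 0.969. Those left without replicate 1 correlated at 0.989, and those without replicate 3 at 0.978. Unequal power therefore stays open. The cause was not tested.

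Of the 54 called genes and features followed by name, 2 kept their call with normexp, 16 with no filter on dim probes, 7 with the replicate block and 36 with subtraction. Without overexpressor replicate 1, 2 or 3 the number was 10, 12 or 11, and without vector control replicate 1, 2 or 3 it was 44, 11 or 42.

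The gibberellin list lost its call with normexp (median 0.0836), subtraction (0.0533), quantile normalization (-0.12), the deposited table (-0.12), the percentile over detected probes (-0.25), the filter on all arrays (-0.23) and trend and robust variance (-0.24), and ranged from -0.29 to -0.19 without 1 array. The glucosinolate list lost it with array weights (-0.0917) and gene-by-gene weights (-0.17), and ranged from -0.33 to -0.0203 without 1 array. The plastid list lost it with array weights (0.0609), gene-by-gene weights (0.0614) and subtraction (0.10). The other 6 lists called kept direction and call under each alternative run with the preset correlation, but not their size, and with an estimated correlation 0 of the 9 lists were called (lowest adjusted p = 0.54). The salicylic acid median of -1.74 was -0.68 with array weights, -0.98 with gene-by-gene weights, -1.07 with normexp and -1.12 with subtraction. The touch and wound median was -0.53 with normexp, the abscisic acid median -0.25 with array weights, and the flavonoid median -0.20 with normexp and with subtraction. Lists not called in the main fit gained a call 15 times over the alternatives that kept every array, and 8 times without 1 array. Among these, the root markers were called with the replicate block and without vector control replicate 3. The cause was not tested for the lists.

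The lowest correlation within a group was 0.982 with no filter on dim probes. The slide as a block could not be run. Dim genes are limited by signal over background.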

Other observations

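The trend of the spike-ins with brightness, the spread of the clock lists, the test on linked loci, the test of single control arrays, the test on the rapid stress list, the splits of the samples and the recount of pairs and the choice of the unnamed features were made after the results were seen. The largest differences belonged to features without a gene symbol. A feature that the array names by position on chromosome 2, minus strand, 3315207 to 3315407, rose by 8.33 (SE 0.11, limma adjusted p = 5.6e-06), and it passed in all 18 alternatives run, with values between 7.74 and 8.42. The genome build of that name is not given in the sources used here. ATRIKEN33667 rose by at least 175-fold, AT5G24240 rose by 5.91 (SE 0.31), and BT025685 fell by at least 180-fold. They passed in 16 of 17, 17 of 18 and 16 of 17 alternatives, and their fitted values came as close to 0 as 4.01, 3.49 and -4.13. AT5G24250, numbered next after AT5G24240, ranged from 0.71 to 3.93 over the alternatives and passed in 10 of 17. AT5G03090 ranged from 2.29 to 3.89 and passed in 17 of 18. AT5G24240 with AT5G24250 was not among the neighbouring pairs counted below. Of 741 tested features named by position, 21 rose and 24 fell. Which of the probes, if any, measures sORF2146 was not settled here.

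The real grouping gave 1209 called genes and the highest of the other splits gave 0. It was 1 of 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. Each other split mixes the groups and slides, so any difference between them enters its residual spread and lowers its count. The contrast of 1209 with 0 therefore decides nothing about chance. A brightness-dependent difference between the slides would move spike-in probes of different brightness apart. The largest departure of any of the 8 from their median shift was 0.35, below the bound of 0.5 set beforehand, but that bound on single probes does not see a trend. The departures fell with brightness, from 0.14 for the dimmest probe to -0.23 for the brightest (Spearman rho -0.86 across probes, exact two-sided permutation p = 0.011). That p-value takes the probes, not the arrays, as units, so the trend is not tested between the slides. Such a difference stays open, above all for the 802 of 1209 calls under 2-fold by fitted value. Slide and group cannot be told apart, as each slide held 1 group.

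The lower mitochondrial dysfunction genes did not rest on 1 control array: the list median closest to 0 was -1.36, without vector control replicate 1. A different time of harvest stays open: the larger absolute median of the clock lists was 0.21, within the bound of 0.3 set beforehand, but morning-phased members went both ways (6 higher, 5 lower, SD 0.42), so their median does not decide. A general rapid stress response of the control plants stays open: the touch and wound list had a median of -0.84, and of -0.49 without vector control replicate 1, but this was known when the test was written and decides nothing. A response to sORF2146 itself also stays open and untested.

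Loci that differ between the plant lines would place genes with changes of 4-fold or more next to each other. By fitted value 4 neighbouring pairs changed the same way: MRD1 with HEI10, MAF4 with MAF5, AT3G28560 with AT3G28570 and AT5G52730 with AT5G52740, and a share of 0.0005 of 10000 random draws had as many (mean 0.38 pairs). Without HEI10, whose probes disagree, 3 pairs were left (share 0.0057), with genes that have only a bound counted at that bound 2 (share 0.0173), and with both changes 1 (share 0.179). The fitted count was thus above that of random placement, but such draws treat neighbouring genes as independent of each other. The count was also known when the test was written and does not hold under both changes together, so linked loci stay open. Cross-hybridization among MADS-box paralogs would raise FLM, MAF2 and MAF3 with MAF4, and the largest of their absolute differences was 0.29, that of MAF2, which was lower; exchange of signal between MAF4, MAF5 and FLC was not tested.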
